A study of Mus musculus with 4 samples.

How the data were processed

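Droplet single-cell RNA sequencing of mouse Achilles tendon was analysed in 4 libraries, 1 per group, each made from 5 pooled tendons per the labels. The groups were Prox1 eGFP at day 0 with no treatment, Prox1 eGFP at days 7 and 21 after the injury, and Vegfc CRE at day 7 after the injury. The injury is abbreviated B/T in the labels and is not expanded here. Per the labels' protocols, tissue was digested with collagenase and dispase and cells were sorted by flow cytometry for Prox1 expression, whereas another label of the same 4 libraries calls the cells unsorted. A Prox1 UMI was found in 96.8% and 86.7% of the cells of Prox1 eGFP days 7 and 21, in 8.85% at day 0 and in 1.15% in Vegfc CRE, so Vegfc CRE was not treated as a library of Prox1-expressing cells. For the others a sort could set the shares of cells given below.

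The deposited matrices held raw counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger 5.0.1 against mm10, per the submitters' processing notes. No normalization or cell annotation by the authors was used. The matrices listed 32285 genes in 3 libraries and 27998 in the Prox1 eGFP day 7 library. The 27040 identifiers found in both lists were kept, which held 99.0%, 99.8%, 99.3% and 99.5% of the UMIs of Prox1 eGFP day 0, day 7, day 21 and Vegfc CRE day 7. Of these shared genes, 1227 carried different symbols in the lists, and 400 overlapped, on the same strand, a gene found in only one list, by the positions of the GENCODE mouse annotation of the same build. A count for such a gene can differ between the lists with no difference in the cells. Transcripts of the eGFP or CRE transgenes were not analysed here. Ccl21a has near-identical copies, so its counts are uncertain.

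The files held 717, 5051, 6704 and 8711 barcodes in the same order of libraries, with 6761289, 59312181, 59894792 and 92568978 UMIs. Cells with at least 500 genes, at least 1000 UMIs and under 15% mitochondrial UMIs were kept, which removed 27, 179, 316 and 1640 barcodes. Scrublet, run per library in scanpy 1.11.5 (Python 3.11.15), called 1, 0, 85 and 101 doublets, or 0.14%, 0.0%, 1.33% and 1.43%, where a rule of 0.8% per 1000 cells gives 0.55%, 3.90%, 5.11% and 5.66%. The caller had therefore not worked on the Prox1 eGFP day 7 library, and removal of the 4, 190, 326 and 400 cells with the highest scores was added as an alternative after the data were seen. This left 689, 4872, 6303 and 6970 cells, 18834 in all, with median UMIs of 7059, 8472.5, 7513 and 8503.5 and median genes of 1960, 2573.5, 2322 and 2446.5.

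Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, scaled and clipped at 10 SD, gave 30 principal components, 15 neighbours and 34 Leiden clusters at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9), with no batch integration. Fixed markers of 20 classes named the clusters. A marker counted where it was at least 2-fold higher and seen in at least 20% of the cluster's cells, and a name needed at least 3 markers and no lead of another class among the top 10 genes by fold. A cluster also stayed unnamed where the next class held over 80% of the best class's share of markers. That rule was set after the clusters were seen, and it kept 0.145%, 0.534%, 3.01% and 4.84% of the cells of the 4 libraries out of a class. In all, 11 clusters stayed unnamed. Muscle-like cells without the mature muscle cluster 19 are called muscle progenitor-like.

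With 1 library per group there is no spread between replicates, so no p-value, standard error or number of changed genes is given between groups. UMIs were summed per library and class and scaled by the UMIs of the group (CPM) with exact Poisson intervals, ratios with exact conditional binomial intervals, and shares of cells with exact Clopper-Pearson intervals. All intervals are 95% intervals and cover counting error only. A count of 0 was given the limit of 3 counts, and a fold against 0 was computed against 3 counts over the group. Such a fold is written as at least that value. It leaves out the counting error of the other library, so it is not a bound of a 95% interval. Shares of cells with a UMI were also given after thinning each cell to 2000 UMIs, leaving out shallower cells. A comparison needed at least 30 cells of the class in both libraries. For gene lists, the median log2 ratio over members with at least 10 UMIs is given with its percentile among 10000 random lists of the same size matched on mean expression, and members at least 2-fold apart are counted by size alone. Of the 20 lists, those named in the text are reported.

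In fibroblast-like cells, cells with and without a Vegfc UMI were summed per library and compared with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using TMM factors, filterByExpr, the quasi-likelihood test, the library as a block and a Benjamini-Hochberg adjusted p under 0.05. The design asked for cells thinned to 2000 UMIs and for at least 20 cells on each side. Thinning left 5 of 263 cells with a Vegfc UMI in Prox1 eGFP day 21 and 10 of 1277 in Vegfc CRE day 7, so unthinned cells, set beforehand as the other choice, were used. The ratio script was tested on simulated Poisson counts for lymphatic endothelial-like cells over 12530 genes, where 95.6% of intervals held the true ratio. That checks the code and not the spread between animals. The edgeR script was tested on simulated data with 200 genes changed 4-fold at a dispersion of 0.02, so smaller changes were not covered. It recovered 98.0% of them with 7 false calls among 203 over 10964 genes for fibroblast-like cells, and 99.5% with 6 false calls among 205 over 10048 genes for muscle progenitor-like cells. DESeq2 1.42.0 recovered 77.5% and 88.5% with 0 false calls.

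Genes were named by a fixed rule. Among genes with at least 100 UMIs in the higher library and a ratio of at least 2, the 8 highest and 8 lowest in fibroblast-like cells, or 5 and 5 in other classes, were taken by the interval bound nearest to 1. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, predicted and sex-linked genes were left out. Members of the fixed lists served as examples, and for the edgeR test the 10 called genes with the smallest adjusted p in each direction and called list members. Some genes that this rule or the lists named are not reported here. Because this ranking was led by genes shifted the same way in all groups compared between days 21 and 7 or by RNA of other cells, a further ranking without genes touched by the differing gene lists, shifted in that way or over 10 times higher in another cluster was added after the data were seen.

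The groups, tests, gene lists, markers, rule for named genes and other settings to try were fixed before the data were examined. These settings were a stricter cell filter (at least 1000 genes and under 10% mitochondrial UMIs), doublet calls kept in, resolutions 0.5 and 2.0, each library clustered on its own, TMM and DESeq2 scaling, equal weight for each cell, gene minimums of 1 UMI in each library and of 50 UMIs, and, for the edgeR test, DESeq2, DESeq2 size factors, no gene filter and no block. Chosen after seeing the data were the comparisons of muscle progenitor-like cells and of cluster 2, all comparisons of Vegfc CRE day 7 with Prox1 eGFP day 21, the Vegfc test in muscle progenitor-like cells, cells matched on depth, cluster 8 alone, cluster 2 added to the lymphatic class, and the other naming rules. Planned comparisons of fibroblast-like and macrophage-like cells among the Prox1 eGFP libraries, and all with day 0, were left out because a library held under 30 cells of the class.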

Results

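What did each library measure? Gene expression was profiled in single cells of mouse Achilles tendon in 4 groups with 1 library each. Prox1 eGFP libraries came from untreated tendon (day 0) and from days 7 and 21 after the injury labelled B/T, and a Vegfc CRE library came from day 7 after it. Prox1 is a transcription factor that sets lymphatic endothelial identity, and eGFP is a fluorescent reporter. CRE is a recombinase, and its use in this line is not given here. Vegfc is a growth factor for lymphatic endothelium that signals through the receptor Flt4. In this order the libraries held 6761289, 59312181, 59894792 and 92568978 UMIs, and 689, 4872, 6303 and 6970 cells were analysed, with median UMIs per cell of 7059, 8472.5, 7513 and 8503.5. There were no replicates, so differences between libraries are given with 95% intervals for counting error only, and no difference could be set against the spread between animals. The labels describe both a sort for Prox1-expressing cells and unsorted cells, and either would bear on the shares of cell types. With a Prox1 UMI in 1.15% of its cells, the Vegfc CRE library was not one of Prox1-expressing cells. On build mm10, Vegfc (ENSMUSG00000031520) lies on chromosome 8 from 54077606 to 54187096 on the plus strand, Prox1 (ENSMUSG00000010175) on chromosome 1 from 190118035 to 190170714 on the minus strand, and Flt4 (ENSMUSG00000020357) on chromosome 11 from 49609263 to 49652739 on the plus strand. All 3 are protein-coding genes.

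Which cell types were recovered before and after injury? The libraries differed in their leading cell classes. At day 0, T/NK-like cells made up 59.4% of 689 cells (55.6 to 63.1%), B/plasma-like cells 14.2% (11.7 to 17.1%) and dendritic-like cells 8.13% (6.2 to 10.4%), while 0.290% were lymphatic endothelial-like. At day 7 of Prox1 eGFP, muscle-like cells, named by Pax7, Myf5 and Myod1 except for a mature cluster of 112 cells named by genes such as Acta1 and Ckm, held 73.9% of 4872 cells (72.6 to 75.1%) and lymphatic endothelial-like cells 8.11% (7.36 to 8.91%). At day 21, muscle-like cells held 54% of 6303 cells (52.7 to 55.2%), lymphatic endothelial-like cells 10.5% (9.71 to 11.2%), fibroblast-like cells 4.22% and tenocyte-like cells 1.90%. In Vegfc CRE day 7, macrophage-like cells held 21.0% of 6970 cells (20.04 to 22%), neutrophil-like cells 19.4% (18.5 to 20.4%), fibroblast-like cells 18.4% (17.5 to 19.3%) and vascular endothelial-like cells 9.43% (8.75 to 10.1%). The same library held 0.029% lymphatic endothelial-like and 0.617% muscle-like cells.

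Vascular endothelial-like cells were 0.698% at day 7 and 1.79% at day 21 of Prox1 eGFP. Tenocyte-like and mural-like cells were 5.25% and 3.33% in Vegfc CRE day 7. Cluster 2 carried all 9 lymphatic markers. Its 10 leading genes held Cldn5, on the fixed vascular marker list, and no lymphatic marker, so the naming rule left it unnamed. It was compared by number and held 571 cells (11.7%) at day 7 and 1107 (17.6%) at day 21. Prox1 stood at 2198 and 1602 CPM and Flt4 at 385 and 283 CPM in cluster 2 on these days. Flt4 in vascular endothelial-like cells was 24 and 22.6 CPM. The lymphatic shares above therefore leave out cells with lymphatic markers. Unnamed cells were 7.98%, 16.5%, 25.1% and 18.1% of the libraries from day 0 to Vegfc CRE. The lymphatic share depended on the clustering and naming. It was 20.01% and 29.4% at days 7 and 21 with resolution 0.5, 11.7% and 26.7% with resolution 2.0, 20.1% and 29.5% with a stricter cell filter, 4.93% at day 7 with a stricter naming rule chosen after seeing the data, and 0.0% at day 7 with each library clustered on its own. In that last setting muscle-like cells were 36.1% and 28.7%. Vegfc CRE fibroblast-like cells were 10.0% at resolution 0.5, and macrophage-like cells 13.8% with doublet calls kept in.

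**Figure D1:**
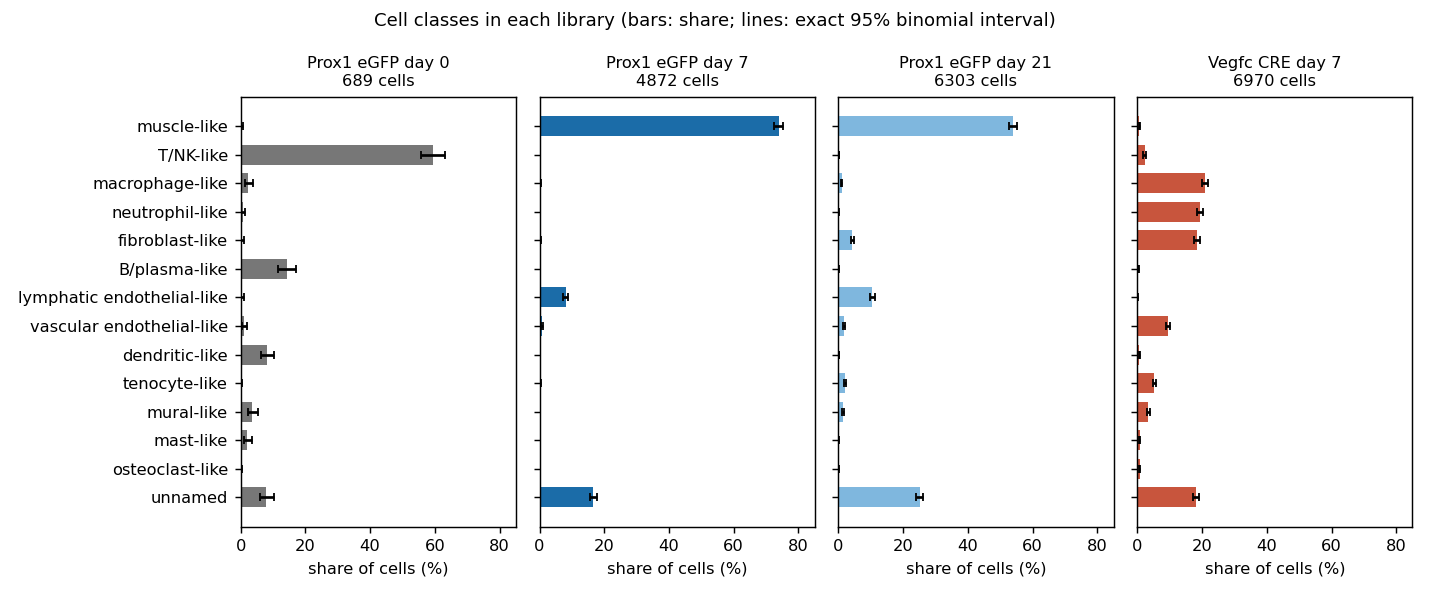
Horizontal bars give the share of cells (%) in each class, with one colour per library, and lines give exact 95% binomial intervals. T/NK-like cells lead at day 0 (59.4%), muscle-like cells at days 7 and 21 of Prox1 eGFP (73.9% and 54%), and macrophage-like cells in Vegfc CRE day 7 (21.0%).

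Which cells held Vegfc, Prox1 and Flt4 transcripts? Among classes of the injured tendons Vegfc was highest in vascular endothelial-like cells, while the 25 cells of cluster 31 at day 0, which took the mural-like name but lead with Ccl19 and Cxcl13, held 121 CPM (83.3 to 170), and Prox1 was high in muscle progenitor-like as well as lymphatic endothelial-like cells. In vascular endothelial-like cells Vegfc stood at 51.0 CPM at day 7 of Prox1 eGFP (35.3 to 71.2, 34 cells), 37.4 CPM at day 21 (27.0 to 50.3, 113 cells) and 12 CPM in Vegfc CRE day 7 (9.71 to 14.7, 657 cells). The ratio to Vegfc CRE was 4.25 (2.78 to 6.34) at day 7 and 3.11 (2.12 to 4.51) at day 21. For day 21 against day 7 of Prox1 eGFP the ratio was 0.73, with an interval that spans 1 (0.46 to 1.19). The class joins clusters 11 and 17. At day 21 these held 57.0 CPM in 60 cells and 4.635 CPM in 53 cells (2 UMIs). Within cluster 11 the ratio of day 21 to day 7 was 0.95 (0.59 to 1.55). In Vegfc CRE the class overlapped 48 osteoclast-like cells, at 9.92 CPM (4.76 to 18.2). Muscle progenitor-like cells held Vegfc at 9.22 CPM (8.14 to 10.4) at day 7 and 11.3 CPM (9.94 to 12.7) at day 21. Fibroblast-like cells held 8.46 CPM (6.10 to 11.4) at day 21 and 3.89 CPM (3.22 to 4.66) in Vegfc CRE. Lymphatic endothelial-like cells held 0.733 CPM (0.317 to 1.45) at day 7 and none in 659 cells at day 21, which allows up to 0.455% of cells with a UMI.

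Prox1 stood at 1250 and 1478 CPM in lymphatic endothelial-like cells of days 7 and 21, where it is one of the class markers, and at 1257 and 775 CPM in muscle progenitor-like cells. In muscle progenitor-like cells, 99.1% and 96.6% held a Prox1 UMI, or 87.4% and 75.4% after thinning. As background, 15.8% of fibroblast-like and 16.9% of macrophage-like cells at day 21 held one (30.8 and 84.6 CPM), at median depths of 18358.5 and 9534 UMIs against 6599 in muscle progenitor-like cells. In Vegfc CRE, 1.79% of fibroblast-like and 0.14% of macrophage-like cells did. Vascular endothelial-like cells held Prox1 at 866 CPM at day 7, 136 CPM at day 21 and 3.16 CPM in Vegfc CRE. Flt4 stood at 448 and 445 CPM in lymphatic endothelial-like cells and at 24, 22.6 and 24.4 CPM in vascular endothelial-like cells of days 7, 21 and Vegfc CRE. Over all cells, Prox1 was seen in 8.85%, 96.8%, 86.7% and 1.15% of the 4 libraries.

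A Vegfc UMI was found in 44.1%, 25.7% and 9.44% of vascular endothelial-like cells of days 7, 21 and Vegfc CRE, and in 17.6%, 6.60% and 1.88% after thinning. In other classes of the same libraries a Vegfc UMI was found in 1.27% of lymphatic endothelial-like cells at day 7 (median 20346 UMIs), in 7.41% of mural-like and 13.9% of fibroblast-like cells at day 21 (9256 and 18358.5 UMIs), in 0 of 59 macrophage-like cells at day 21 (up to 5.08%, 9534 UMIs) and in 0.07% of macrophage-like cells in Vegfc CRE (8889 UMIs). Higher shares were found in tenocyte-like cells at day 21 (15.8%, 23613 UMIs). In Vegfc CRE they were 7.96%, 7.1% and 14.6% in fibroblast-like, tenocyte-like and osteoclast-like cells, at medians of 22650, 24847 and 18961.5 UMIs. After thinning these were 0.78%, 0.82% and 0.0%. The vascular endothelial-like class had medians of 20423.5 UMIs at day 7 and 9840 in Vegfc CRE. When each library was clustered on its own, that class took in other cells and the log2 ratio of Vegfc in Vegfc CRE against day 7 was 1.24 instead of −2.10.

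**Figure D2:**
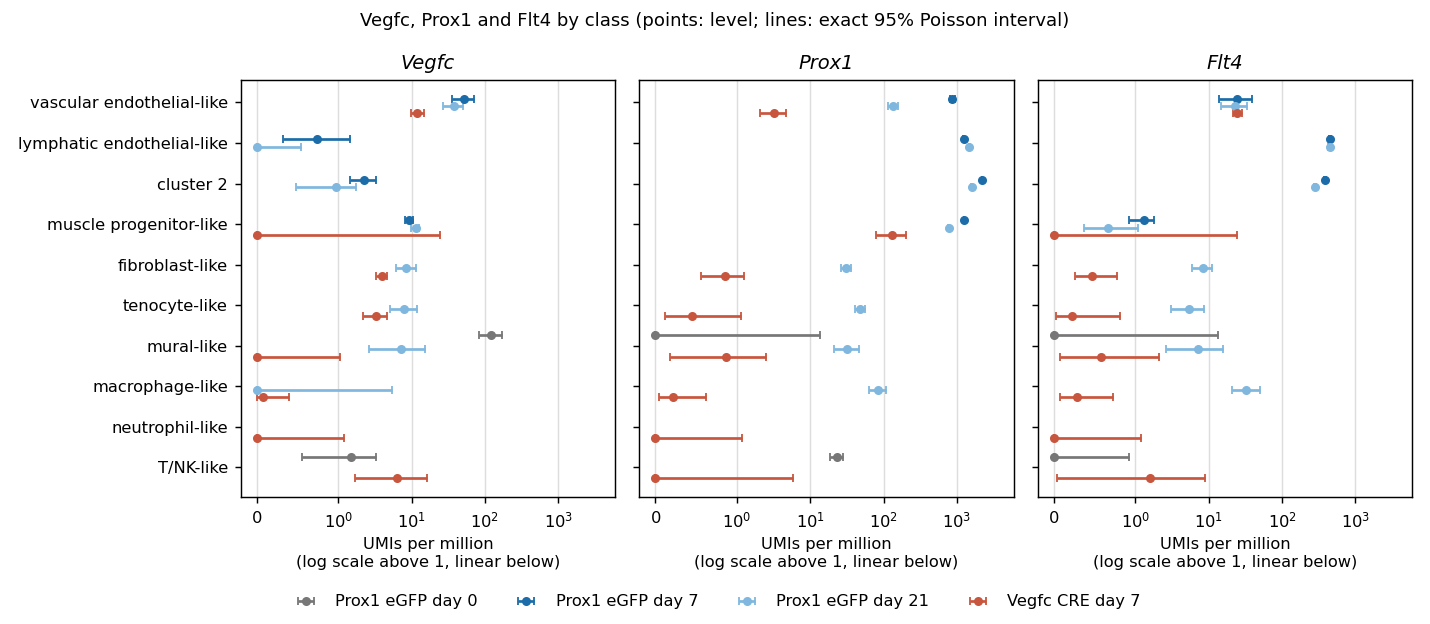
Points give Vegfc, Prox1 and Flt4 in CPM (logarithmic above 1, linear below) for each cell group with at least 20 cells, coloured by library, and lines are exact 95% Poisson intervals. Vegfc reaches 51.0 and 37.4 in vascular endothelial-like cells of days 7 and 21 of Prox1 eGFP against 12 in Vegfc CRE, and Prox1 stands at 1257 and 775 in muscle progenitor-like cells of those days.

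How did lymphatic endothelial-like cells differ between days 21 and 7 of Prox1 eGFP? Genes of cell division were lower at day 21 in 659 cells than at day 7 in 395 cells. Of 16 proliferation genes, 12 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of −1.27 (−1.33 to −1.19) at percentile 0.0 of matched random lists. Mki67, a marker of cycling cells, stood at 58.4 against 198 CPM (3.39-fold lower, 3.04 to 3.78), Top2a, which untangles replicated DNA, was 2.59-fold lower (2.39 to 2.81), and Birc5, needed for mitosis, was 2.52-fold lower. Pcna, the DNA polymerase clamp, was level at 88.0 and 86.2 CPM. Outside the lists, the histone gene Hist1h2ap was 5.81-fold lower (5.22 to 6.48) and the kinetochore motor gene Cenpe 4.18-fold lower (3.56 to 4.93).

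Among lymphatic markers, which also define the class, 1 of 7 was at least 2-fold higher and the median was 0.51 (percentile 99.8). Ccl21a, a chemokine that draws leukocytes into lymphatics, stood at 25430 against 10470 CPM, the hyaluronan receptor gene Lyve1 at 3041 against 1859 and Mmrn1 at 1536 against 942, while Flt4 was level at 445 and 448. Endothelial tip and growth genes had a median of −0.41 (percentile 0.62), with 2 of 12 at least 2-fold lower. The basement membrane collagen genes Col4a1 and Col4a2 stood at 579 against 813 and 276 against 417 CPM, and the VEGF receptor gene Kdr at 359 against 369.6. Glycolysis and hypoxia genes had a median of −0.37 (percentile 0.93), with 2 of 18 at least 2-fold lower, 1 higher, and Pkm and Ldha, enzymes of late glycolysis, at 173 against 391 and 267.5 against 476 CPM. VEGF ligands and receptors had a median of −0.13 (percentile 34.5, 1 of 8 at least 2-fold lower), with Pgf, a VEGF family ligand, at 34.7 against 56.0 CPM. Outside the lists, Fst, which encodes the activin antagonist follistatin, was 4.63-fold higher (3.81 to 5.66) and Glycam1 28.4-fold lower (13.6 to 71.2). Dissociation and immediate early genes had a median of 0.19 (percentile 98.4). Fibrillar collagen genes, of other cells, moved as much as the lymphatic markers, with a median of 0.52 (percentile 99.4, 1 of 8 at least 2-fold higher). Complement genes had a median of 0.62 (percentile 99.6, 2 of 7 higher, 1 lower). Resting fibroblast and tendon genes had medians of 0.09 (percentile 81.6) and −0.25 (percentile 28.4). The class joins cluster 8 with the dividing cluster 18, which held 155 of 395 cells at day 7 and 71 of 659 at day 21, and in cluster 8 alone, an alternative chosen after seeing the data, the medians were −0.74 for proliferation, −0.01 for lymphatic markers and −0.46 for dissociation genes. Cells of day 7 were deeper, at a median of 20346 against 8419 UMIs.

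How did cluster 2 differ between these days? Interferon response genes had a lower median at day 21 in 1107 cells than at day 7 in 571, as had, by less, genes of TGF-beta and BMP signalling. The interferon median was −0.76 (−0.89 to −0.61, percentile 0.0), with 5 of 14 members at least 2-fold lower and 0 higher. The antiviral gene Rsad2 was 15.4-fold lower (9.30 to 27.4) and Ifit1 2.84-fold lower (2.41 to 3.36), while Isg15 stood at 161.5 against 209.9 CPM. The median of TGF-beta and BMP genes was −0.50 (−0.56 to −0.33, percentile 0.03), with 4 of 16 at least 2-fold lower and 1 higher. Smad7, a feedback inhibitor, was 2.58-fold lower, Id1 and Id3, targets of BMP signalling, stood at 161 against 266 and 787 against 1261 CPM, Tgfb1 at 166 against 259, and Tgfb2 was the member higher, at 57.5 against 28.7 CPM.

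Endothelial tip and growth genes had a median of −0.43 (percentile 0.38, 1 of 12 at least 2-fold lower) with Col4a2 2.11-fold lower (2.0 to 2.22) and Plvap, a gene of fenestrated endothelium, at 834 against 1410 CPM. Proliferation genes had a median of −0.60 (percentile 0.525, 3 of 15 at least 2-fold lower). The 7 lymphatic markers had a median of −0.15 (percentile 11.9), with Prox1 at 1602 against 2198 CPM and Ccl21a at 10780 against 5977. Glycam1 was 8.74-fold lower (7.44 to 10.3) and Bmp6, a BMP ligand gene, 7.93-fold higher (5.30 to 12.3). The 6 MHC class II genes were all at least 2-fold higher at day 21 (median 4.46, percentile 100), at low levels such as 75.9 against 3.23 CPM of Cd74, beside genes of other cells, with 4 of 11 resident and repair macrophage genes (median 0.34) and 5 of 13 resting fibroblast genes (median −0.03) at least 2-fold higher. Dissociation genes had a median of 0.28 (percentile 99.99), and cells of day 7 were deeper (18888 against 9508 UMIs). TMM scaling placed the centre of all genes at −0.19, under which the interferon median was −0.56. Against that centre the lymphatic marker median is above 0.

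How did muscle progenitor-like cells differ between days 21 and 7? Genes of inflammatory cytokines and chemokines were lower at day 21 in 3303 cells than at day 7 in 3486, with 11 of 19 at least 2-fold lower, 2 higher and a median of −1.16 (−1.45 to −0.97, percentile 0.0). Ccl4 and Ccl11, which attract leukocytes, were 38.4-fold (18.4 to 96.3) and 10.4-fold lower (8.35 to 13.1), Ccl7 3.11-fold and the cytokine gene Il6 2.95-fold lower (2.49 to 3.51), and Ccl2 stood at 46.0 against 90.6 CPM. Cxcl1, a neutrophil attractant, was level at 1100 and 1150 CPM. VEGF ligands and receptors had a median of −0.71 (percentile 2.04), with 3 of 10 at least 2-fold lower. Vegfa, the main angiogenic ligand, was 2.5-fold lower (2.27 to 2.77), whereas the ratio of Vegfc was 1.22 (1.03 to 1.46). Interferon response genes had a median of −0.68 (−0.78 to −0.48, percentile 0.59, 2 of 14 at least 2-fold lower), with Gbp2 at 10.5 against 22.9 CPM.

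TGF-beta and BMP genes had a median of −0.45 (percentile 1.10, 1 of 16 at least 2-fold lower). Tgfb2 stood at 62.2 against 132 CPM, Id2 at 77.3 against 154 and Bmp4 at 154 against 268. Sox9 and Sox6, transcription factors of cartilage, stood at 81.3 against 162.5 and 2.54 against 7.67 CPM, within 4 chondrogenic genes whose median was −1.08 (percentile 0.79, 2 at least 2-fold lower) but 0.31 with a minimum of 1 UMI in each library. Prox1 was 1.62-fold lower (1.59 to 1.65). Proliferation genes had a median of −0.01 (percentile 94.5, 1 of 16 at least 2-fold higher), with Mki67 at 1.58 against 1.62 CPM. Outside the lists, Olfm2 was 25-fold (17.6 to 36.6) and Mpp7 6.09-fold higher (5.54 to 6.71), and Gpc3, a heparan sulfate proteoglycan gene, 10.9-fold lower (8.32 to 14.5). Fosb and Atf3, early response genes of the dissociation list, stood at 1324 against 4169 and 1159 against 528 CPM. Dissociation genes as a list had a median of −0.11 (percentile 23.5), and genes of other cell types were higher at day 21, with medians of 1.31 for 14 resting fibroblast genes (8 at least 2-fold higher) and 0.97 for 8 tendon genes (4 higher), at levels such as 35.8 against 6.25 CPM of Dcn. The cells came mostly from clusters 1 and 3 at day 7 and from clusters 0 and 9 at day 21. TMM scaling placed the centre of all genes at −0.22, under which the inflammatory median was −0.95 and the medians of proliferation and dissociation genes turned positive.

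How did vascular endothelial-like cells compare between the libraries? Against day 7, with 34 cells, the 113 cells of day 21 were lower in proliferation genes (median −1.49, −2.31 to −1.15, percentile 0.0, 8 of 12 at least 2-fold lower) and the median of endothelial tip and growth genes was 0.66 (0.29 to 0.84, percentile 100), with 3 of 15 at least 2-fold higher. Top2a was 0 at day 21 and 51.0 CPM at day 7, at least 19.6-fold lower, Mki67 was 12.1-fold lower (3.61 to 63.2) and Stmn1, a microtubule regulator, 2.96-fold lower (2.11 to 4.19). Within the tip and growth list, the ratio of Apln, a ligand of sprouting endothelium, was 6.18 (1.93 to 31.6), resting on 3 UMIs at day 7. Col4a1 stood at 977 against 544 CPM, whereas Plvap was 1.68-fold lower (1.58 to 1.80). Cxcl12, a chemokine gene, was 3.90-fold higher (3.38 to 4.51), Sele, a leukocyte adhesion receptor gene, 5.30-fold higher (3.34 to 8.89), and Sox17, a transcription factor of arterial endothelium, 4.84-fold higher (3.13 to 7.82). Interferon response genes had a median of 0.53 (percentile 99.99, 4 of 14 at least 2-fold higher, 1 lower), with Isg15 at 243 against 162 CPM. Lymphatic markers, which are genes of another class, had a median of 2.04 (4 of 6 at least 2-fold higher, 1 lower), while Prox1 was 6.39-fold lower (5.35 to 7.68), and MHC class II genes had a median of 4.59 (6 of 6 higher).

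Against the same 34 cells, the 657 cells of Vegfc CRE day 7 were higher in tip and growth genes (median 1.67, 1.08 to 1.83, percentile 100), with 9 of 15 at least 2-fold higher and 2 lower. Apln stood at 66.2 against 4.50 CPM (14.7-fold, 5.01 to 71.6), its receptor gene Aplnr at 664 against 103, the tip cell gene Esm1 at 21.6 against 4.50 and Col4a1 at 2274 against 544, whereas Plvap was 2.45-fold lower (2.33 to 2.58). Proliferation genes had a median of 0.89 (percentile 100, 6 of 16 at least 2-fold higher), with Ube2c, a mitotic ubiquitin enzyme gene, 14.2-fold (5.53 to 52.4) and the kinase gene Cdk1 4.79-fold higher (2.41 to 11.2). Sema3g, a semaphorin gene, had a ratio of 35.5 (6.34 to 1405). Prox1 and Cytl1 were lower by 274-fold (184 to 427) and 78.5-fold (63.5 to 98.0). A Prox1 UMI was seen in 85.3% of the 34 cells and in 2.89% of the 657. The libraries thus differ in line and in the share of Prox1-expressing cells at once, and these cannot be told apart here. Inflammatory genes had a median of 1.72 (10 of 17 at least 2-fold higher, 3 lower) that was −0.23 with a minimum of 1 UMI in each library, and Cxcl1 was 4.29-fold lower. Genes of other cells moved with it, with medians of 1.72 for inflammatory monocyte genes (8 of 11 higher, 1 lower), 2.04 for resident and repair macrophage genes (6 of 10 higher, 1 lower) and 3.07 for MHC class II genes (5 of 6 higher), or 0.17, −0.11 and 2.0 with genes at 0 set to the floor. Lymphatic markers had a median of −1.63 (percentile 0.37, 4 of 6 at least 2-fold lower) and dissociation genes of −1.50 (12 of 16 lower, 1 higher).

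Against day 21, Vegfc CRE vascular endothelial-like cells were higher in proliferation genes (median 3.48, 3.01 to 4.83, percentile 100, 14 of 16 at least 2-fold higher, and 3.03 with the genes at 0 set to the floor of 3 counts). Ube2c, Birc5 and Hist1h2ap were 0 in the 113 cells of day 21 and 85.3, 66.1 and 108.5 CPM in Vegfc CRE, at least 32.7-fold, 25.4-fold and 41.6-fold higher, and Mest, an imprinted gene, was 19.7-fold higher (12.6 to 32.8). Interferon genes were lower (median −0.88, percentile 0.0, 6 of 14 at least 2-fold lower), with Isg15 2.13-fold and Rsad2 2.45-fold lower (1.93 to 3.10). Bmp4 was 6.91-fold (5.63 to 8.48), Timp4, a protease inhibitor gene, 9.15-fold (7.96 to 10.5) and the early response gene Fos 6.42-fold lower (6.09 to 6.78), within dissociation genes whose median was −1.96 (13 of 16 lower, 1 higher). RNA of other cells moved in this comparison, with medians of −3.89 for lymphatic markers (5 of 6 at least 2-fold lower) and 1.30 for fibrillar collagen genes (9 of 12 higher), and MHC class II genes had a median of −1.92 (6 of 6 lower). The class joins cluster 11 with cluster 17, which leads with genes such as Timp4, and these held 30 and 4 cells at day 7, 60 and 53 at day 21, and 489 and 168 in Vegfc CRE. The median share of mitochondrial UMIs was 3.72%, 3.01% and 5.29% in this order. A Prox1 UMI was seen in 85.3%, 27.4% and 2.89% of these cells. Day 21 and Vegfc CRE differ in day and line as well. The 34 cells of day 7 also held muscle and matrix RNA, such as Ckm at 412 CPM against 3.48 at day 21, Tnnc2 at 742 against 0.758 in Vegfc CRE and Col1a1 at 496 against 15.6 at day 21. TMM scaling placed the centre of all genes at −0.16, −0.31 and −0.14 in these 3 comparisons. With each library clustered on its own, the proliferation medians turned to 4.31 for day 21 against day 7 and −1.73 for Vegfc CRE against day 21, and the lymphatic median of day 21 against day 7 to −0.99.

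**Figure D3:**
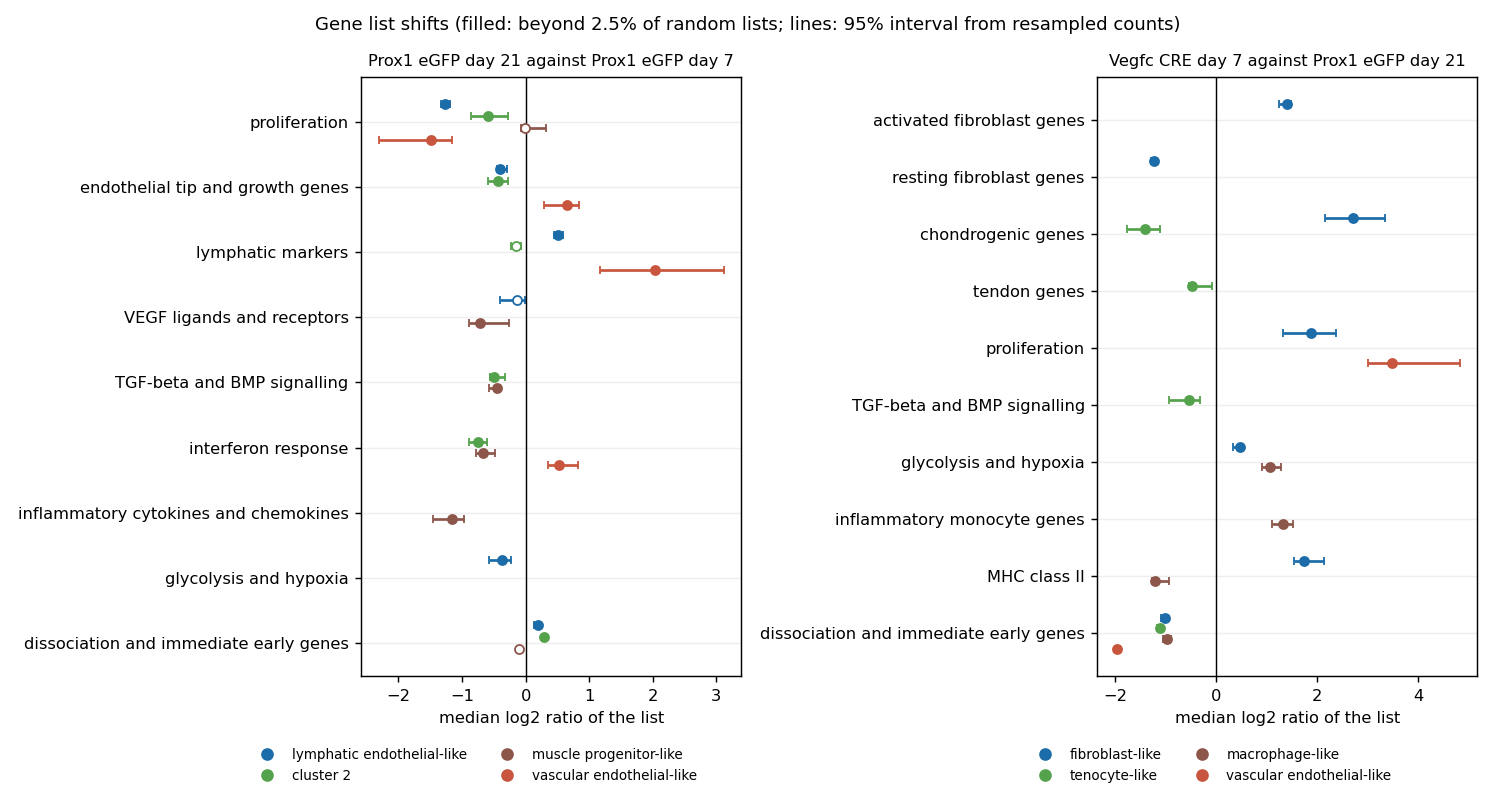
Points are median log2 ratios of gene lists within a class, with day 21 against day 7 of Prox1 eGFP in one panel and Vegfc CRE day 7 against Prox1 eGFP day 21 in the other, and lines are 95% intervals from resampled counts. Filled points lie outside the central 95% of matched random lists, such as proliferation in lymphatic endothelial-like cells (−1.27) and activated fibroblast genes in fibroblast-like cells (1.40).

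How did fibroblast-like cells of Vegfc CRE day 7 compare with those of Prox1 eGFP day 21? These libraries differ in day, line and cell recovery at once, and the median share of mitochondrial UMIs was higher in Vegfc CRE, at 4.48% against 1.99% in fibroblast-like, 4.8% against 1.99% in tenocyte-like and 4.67% against 2.25% in macrophage-like cells. Genes of activated fibroblasts were higher and genes of resting fibroblasts lower in Vegfc CRE (1282 cells) than at day 21 (266 cells). The activated median was 1.40 (1.24 to 1.48, percentile 100), with 8 of 15 at least 2-fold higher and 0 lower. Acta2, the smooth muscle actin gene, was 11-fold higher (9.90 to 12.3), the matrix genes Tnc and Col12a1 9.01-fold (7.97 to 10.2) and 3.40-fold higher (3.16 to 3.66), and Timp1 2.72-fold higher (2.61 to 2.84). Postn, a matrix gene, stood at 4110 against 3070 CPM and the proteoglycan gene Aspn at 904 against 1569. The resting median was −1.23 (−1.29 to −1.19, percentile 0.0), with 9 of 15 at least 2-fold lower and 0 higher. Gsn was 4.26-fold (4.19 to 4.34), Igfbp6 3.73-fold, Clec3b 3.23-fold and Pi16, a gene of adventitial fibroblasts, 2.35-fold lower (2.28 to 2.42), and Fbn1, the fibrillin gene, stood at 1078 against 1297 CPM.

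Proliferation genes were higher (median 1.89, 1.61 with genes at 0 set to the floor, percentile 100, 10 of 16 at least 2-fold higher), with Cdk1 at 11.7 against 2.01 CPM. Chondrogenic genes had a median of 2.72 (10 of 12 at least 2-fold higher), with Acan, the cartilage proteoglycan gene, at 106 against 17.9 CPM and Sox9 at 99.9 against 53.4, but −4.64, with a log2 ratio of −0.76 for Acan, when each library was clustered on its own. Glycolysis genes had a median of 0.46 (percentile 99.97, 6 of 18 at least 2-fold higher, 1 lower), with Pkm 2.39-fold and Eno1 2.64-fold higher and Hk2 2.60-fold lower. Spp1, the osteopontin gene, Saa3, an acute phase gene, and the neutrophil chemokine gene Cxcl5 were 61.3-fold (43.6 to 89.1), 35.6-fold (27.6 to 46.8) and 18.2-fold higher (15.4 to 21.5), and Gzmd, a granzyme gene, was at least 43.7-fold higher. Myoc, Smpd3 and Lsamp were 15.5-fold (14.6 to 16.6), 9.58-fold and 7.77-fold lower. Vegfc was 2.17-fold lower (1.49 to 3.12) and Vegfd level at 64.2 and 66.3 CPM. RNA of other cells moved with these groups. Lymphatic markers had a median of −5.14, with Ccl21a at 0 in Vegfc CRE against 243 CPM (at least 2461-fold lower), the neutrophil gene S100a9 stood at 132 against 0.403 CPM, and 5 of 6 MHC class II genes were at least 2-fold higher (median 1.75). Resident and repair macrophage genes, a list that holds Spp1, had a median of 0.92 (6 of 14 at least 2-fold higher, 2 lower). Inflammatory monocyte genes had a median of 0.64 (5 of 11 at least 2-fold higher). Dissociation genes had a median of −1.02 (9 of 16 at least 2-fold lower, 1 higher). The class holds clusters 6 and 10 in Vegfc CRE but almost only cluster 6 at day 21, and cluster 10 leads with Cxcl5, Saa3 and Tnc. With each library clustered on its own the activated and resting medians were 0.84 and −0.52.

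How did tenocyte-like cells compare between the same libraries? Chondrogenic genes had a lower median in 366 cells of Vegfc CRE than in 120 cells of day 21, as had, by less, genes of TGF-beta and BMP signalling. The chondrogenic median was −1.41 (−1.77 to −1.11, percentile 0.0), with 8 of 13 at least 2-fold lower and 1 higher. Col10a1, a collagen gene of hypertrophic cartilage, was 0 in Vegfc CRE and 49.1 CPM at day 21, at least 146-fold lower, Hapln1 was 5.64-fold (3.89 to 8.28) and Col2a1 2.66-fold lower (2.09 to 3.38), Sox9 stood at 82.8 against 88.9 CPM, and Acan was 2.64-fold higher (2.41 to 2.90). Of 17 TGF-beta and BMP genes, 7 were at least 2-fold lower and 1 higher (median −0.53, percentile 0.155). Ccn2, a matricellular target gene, was 8.81-fold (8.02 to 9.68), Id1 8.27-fold and Id3 5.95-fold lower (5.47 to 6.48), and Tgfbi was 4.20-fold higher (3.79 to 4.66). Of 11 tendon genes, which include class markers, 2 were at least 2-fold lower (median −0.47, percentile 0.35), with Chad and Cilp2, matrix genes, 8.77-fold and 3.75-fold lower, Tnmd, the tenomodulin gene, at 1007 against 1438 CPM and the tendon transcription factor gene Scx at 377 against 350.3. The collagenase gene Mmp13 was 7.45-fold higher (6.40 to 8.73), Wfdc18 had a ratio of 91.5 (31.2 to 445), and Igfbp2 was 23.3-fold lower (15.2 to 37.2). RNA of other cells also moved with the groups, with medians of −4.60 for lymphatic markers (6 of 7 at least 2-fold lower), 2.41 for MHC class II genes (5 of 6 higher) and 1.46 for inflammatory monocyte genes (5 of 9 higher). Dissociation genes had a median of −1.10 (10 of 16 at least 2-fold lower, 2 higher). With each library clustered on its own the chondrogenic median was 1.45.

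How did macrophage-like cells compare? Genes of glycolysis and of inflammatory monocytes were higher, and genes of MHC class II lower, in 1463 cells of Vegfc CRE than in 59 cells of day 21, while genes of resident and repair macrophages went both ways. The glycolysis median was 1.07 (0.90 to 1.28, percentile 100, 10 of 18 at least 2-fold higher, 2 lower, 0.975 with genes at 0 set to the floor) and 0.59 with doublet calls kept in. Pkm was 3.02-fold higher (2.58 to 3.56), Pfkl, a phosphofructokinase gene, 5.21-fold higher (2.22 to 16.1), the ratio of Slc2a1, a glucose transporter gene, was 7.28 (2.0 to 60.3), and Hk2 was 2.39-fold lower. Of 12 inflammatory monocyte genes, 8 were at least 2-fold higher (median 1.32, percentile 100), with Thbs1 4.74-fold and Clec4e, a pattern receptor gene, 10.9-fold higher (5.02 to 29.9), Ccr2, a monocyte chemokine receptor gene, at 204 against 117 CPM and Ly6c2 at 8.82 against 11.9. Resident and repair genes had a median of −0.69 (percentile 0.01), with 5 of 16 at least 2-fold lower and 4 higher. Lyve1 was 6.61-fold (5.50 to 7.91), Mmp12, the macrophage elastase gene, 4.18-fold and Cd163, a scavenger receptor gene, 2.26-fold lower, and Mrc1 stood at 873 against 1621 CPM, while Arg1, the arginase gene, was 0 at day 21 and at least 45.1-fold higher and Spp1 3.81-fold higher (3.50 to 4.16). Of 7 MHC class II genes, 4 were at least 2-fold lower (median −1.21, percentile 0.01), with Cd74 2.66-fold and H2-Aa 2.31-fold lower. Complement genes had a median of −0.58 (percentile 1.67, 1 of 11 at least 2-fold lower, 1 higher). Outside the lists, the lectin gene Mgl2 was 10.8-fold lower (9.03 to 13), and the ratio of Saa3 was 76.1 (13.6 to 3009), resting on 1 UMI at day 21. The ratio of the chemokine gene Cxcl3 was 53.8 (9.64 to 2128), also resting on 1 UMI at day 21. Inflammatory cytokine and chemokine genes as a list had a median of 0.078 (5 of 17 at least 2-fold higher, 3 lower). RNA of other cells moved with the groups, with medians of −6.72 for lymphatic markers (6 of 7 at least 2-fold lower), which include Lyve1, −1.26 for resting fibroblast genes (8 of 15 lower, 4 higher) and −2.07 for tendon genes (5 of 7 lower). The class joins cluster 5 with cluster 14, which leads with Ccl8, Folr2, Mrc1 and Cd163, and these held 1087 and 376 cells in Vegfc CRE but 26 and 33 at day 21. Dissociation genes had a median of −0.96 (7 of 16 at least 2-fold lower). TMM scaling placed the centre of all genes at −0.19.

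How did fibroblast-like cells with a Vegfc UMI differ from those without? Resting fibroblast genes were lower in cells with a Vegfc UMI in the main fit, but by less with cells matched on depth. The test compared 37 with 229 cells at day 21 and 102 with 1180 in Vegfc CRE, summed per library, and edgeR's quasi-likelihood test called 28 of 10946 genes at a Benjamini-Hochberg adjusted p under 0.05, 6 higher and 22 lower, with 560 at an unadjusted p under 0.05. All 15 resting fibroblast genes had a negative log2 change (median −0.49), 8 were called and 12 when adjusted over the list alone. Igfbp6 (−0.89, adjusted p = 0.000108), Pi16 (−0.92, adjusted p = 0.00526) and Gsn (−0.49, adjusted p = 0.00526) were lower in 2 of 2 libraries, as were Ly6c1, Cd55, Ly6a, Clec3b and Cd34. Of 15 activated fibroblast genes, Timp1 (0.43, adjusted p = 0.0191) and Tnc (0.57, adjusted p = 0.049) were higher in 2 of 2 libraries, and 8 passed when adjusted over the list alone, 7 of them higher (median 0.21). Other called genes were Cxcl9 (1.59) and Fibin (0.69), higher, and Rgs5 (−2.52), a pericyte gene, Acp5 (−1.04), Cadm3 (−1.54) and Scara5 (−1.01), lower. Of 6 lymphatic markers, 2 were higher, Ccl21a (2.71), whose UMIs all came from day 21, and Mmrn1 (2.27), and 3 passed when adjusted over the list alone. Ccl21a had the smallest adjusted p of the called genes. Mmrn1 had 71 UMIs in cells with and 87 in cells without a Vegfc UMI at day 21, against 3 and 0 in Vegfc CRE. Lymphatic markers are genes of another class, and whether RNA of other cells moved them here was not tested.

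Cells with a Vegfc UMI were deeper, at medians of 20985 against 17815 UMIs at day 21 and 27555 against 22182 in Vegfc CRE. In Vegfc CRE the class joins 695 cells of cluster 6, which leads with Pi16 and Clec3b, with 587 of cluster 10, which leads with Tnc among others. Over all libraries these clusters had medians of 18883.5 and 28648 UMIs. The test did not set them apart, so a different mix of the clusters could move these genes. With cells matched on depth, chosen after seeing the data, edgeR called 15 genes, of which 6 were among the 28 (Ccl21a, Wfdc18, Igfbp6, Pi16, Acp5 and Mmrn1), resting genes had a median of −0.16 with 2 called and activated genes a median of 0.00 with 0 called. The fit rests on 2 libraries and 1 residual degree of freedom. DESeq2 called 2 genes (73 at an unadjusted p under 0.05), edgeR without the library as a block called 0 (39 unadjusted), and edgeR with only genes without counts removed called 98.

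In muscle progenitor-like cells, a comparison chosen after seeing the data, edgeR called 7 of 10106 genes between thinned cells with and without a Vegfc UMI (69 and 3396 cells at day 7, 56 and 3205 at day 21), with 428 at an unadjusted p under 0.05. All 7 were lower with Vegfc. Among them were Nppc, a natriuretic peptide gene (−0.61, adjusted p = 2.77e-06), Gas1 (−0.48, adjusted p = 0.000408), Nap1l1 (−1.51), Crip1 (−0.52) and Actb (−0.27), each lower in 2 of 2 libraries, and Fos (−0.24), lower in 1 of 2. DESeq2 called 0 (52 unadjusted), edgeR without the block 0 (301 unadjusted), edgeR with DESeq2 size factors 2, edgeR with doublet calls kept in 2, edgeR on unthinned cells 39 (21 higher, 18 lower), and edgeR on depth-matched unthinned cells 42 (26 higher, 16 lower), with Fos the only one of the 7 among them.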

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

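Results are given here because an effect ran in opposite directions in different cell groups or because a signal lay in genes left out of the comparisons. Tests named below as written beforehand had their predictions set before their values were computed, and all other tests were chosen only after the result was seen.

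Between days 21 and 7 of Prox1 eGFP, endothelial tip and growth genes had a median log2 ratio of −0.41 in lymphatic endothelial-like cells, −0.43 in cluster 2 and 0.66 in vascular endothelial-like cells. Interferon response genes had medians of −0.76 in cluster 2, −0.68 in muscle progenitor-like cells and 0.53 in vascular endothelial-like cells. Between Vegfc CRE day 7 and Prox1 eGFP day 21, chondrogenic genes had medians of 2.72 in fibroblast-like and −1.41 in tenocyte-like cells, and MHC class II genes 1.75 in fibroblast-like and −1.21 in macrophage-like cells. With each library clustered on its own, both chondrogenic medians turned, to −4.64 and 1.45. With 1 library per group, none of these differences between cell groups was tested.

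At day 0, the lymphocyte genes Trac, Trbc2, Igkc and Ighm, which are missing from one of the gene lists and so from the comparisons, stood at 478, 1227, 836.5 and 434 CPM over all cells. They stood at 0.86, 1.86, 0.447 and 4.18 CPM at day 21 and at 3.62, 9.45, 271 and 28.5 CPM in Vegfc CRE.

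The day 0 library held mostly T/NK-like, B/plasma-like and dendritic-like cells. Cells of a lymph node in the sample are a candidate explanation: in a test written beforehand, 8 of 10 lymphoid stroma genes were at least 2-fold higher in the 25 cells of cluster 31 than in mural-like and fibroblast-like cells of the other libraries, all except Cr2 and Ltbr. For blood, in a test chosen after the result was seen, 0.581% of day 0 cells were neutrophil-like. Hbb-bs stood at 0.0 CPM against 69.9 in Vegfc CRE. These values argue against whole blood, but a sort could also set them, so lymphocytes of blood are not excluded. A gate that let cells without Prox1 through remains open, since 8.85% of day 0 cells held a Prox1 UMI against 96.8% and 86.7% at days 7 and 21, which an unsorted sample would also give. Resident lymphocytes of uninjured tendon were not tested as a biological explanation.

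Between days 21 and 7, 100 genes were shifted at least 4-fold the same way in lymphatic endothelial-like cells, cluster 2 and muscle progenitor-like cells, 70 higher and 30 lower, and leaned the same way in vascular endothelial-like cells, where 68 had enough UMIs to compare. Among them were Atp6v0c, Rnasek, Tonsl and Ptp4a1. Different gene lists are a likely cause for part of them, since 39.0% (29.4 to 49.3%) overlapped a gene of only one list, against 2.03% of 11636 other genes. The day after injury, the biological explanation, stays open for part of them, since in fibroblast-like cells of Vegfc CRE, also of day 7, against day 21, 14.6% (8.2 to 23.3%) of 96 lay at least 2-fold toward day 7, against 5.73% of 11490 other genes. A test written beforehand gave 92.3% of 91 shifted in vascular endothelial-like cells of Vegfc CRE against day 7, and is not used because the same 34 cells of day 7 had helped to choose the genes.

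Vegfc was higher in vascular endothelial-like cells of the Prox1 eGFP libraries than in those of Vegfc CRE, although with each library clustered on its own, which names other cells, the log2 ratio of Vegfc CRE to day 7 turned from −2.10 to 1.24. Among other groups with at least 30 cells at day 7, the highest, cluster 0, held 14.8 CPM. That lies below the interval of the vascular class (35.3 to 71.2) and argues against RNA of those groups as the source. Smaller groups were not covered, such as 7 fibroblast-like cells of day 7, of which 3 held a Vegfc UMI. The check was not made at day 21, so RNA of other cells is not excluded. A different mix of vascular clusters was excluded for day 7, since the ratio of day 7 to Vegfc CRE within cluster 11 was 5.02 (3.25 to 7.62). For selection of Prox1-positive vascular cells by a sort, the test written beforehand asked for higher Vegfc in cells with a Prox1 UMI, beyond counting error. At day 21 the ratio between 31 cells with and 82 without a Prox1 UMI was 1.99 (1.04 to 3.79), which met that prediction. A further condition, the same within cluster 11, was added after this ratio was seen. There, with 26 and 34 cells, the ratio was 1.37 (0.71 to 2.66), which did not meet it. Selection therefore stays open. A difference between the mouse lines was not tested and stays open, and Vegfc was also lower in Vegfc CRE than at day 21 in fibroblast-like (3.89 against 8.46 CPM) and tenocyte-like cells (3.26 against 7.96 CPM).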

How the results depend on the processing

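Alternatives named here as added were chosen only after the results were seen. Of 408 alternative values of class shares, 265 stayed within counting error and 143 moved. Of 550 for gene lists, 415 stayed, 125 moved and 10 reversed, and of 1244 for single genes, 876 stayed, 360 moved and 8 reversed. CPM of Vegfc, Prox1 and Flt4 stayed in 94 of 114. These cover only the stricter cell filter, doublet calls kept in and the highest doublet scores removed (added). The other resolutions and clustering each library on its own are not in that count. Shares with a UMI, counted for thinning only, stayed in 12 of 40. Intervals cover counting error only, so a move past them is common at this depth. The cause was not tested for any value below unless stated. List values are median log2 ratios.

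At resolution 0.5, T/NK-like cells at day 0 were 54.9%, lymphatic endothelial-like cells 20.01% and 29.4% at days 7 and 21, muscle-like cells 77.5% and 56.0%, and Vegfc CRE fibroblast-like cells 10.0%. At resolution 2.0, lymphatic endothelial-like cells were 11.7% and 26.7% and Vegfc CRE macrophage-like cells 18.1%. With the stricter cell filter, lymphatic endothelial-like cells were 20.1% and 29.5%, muscle-like cells 77.7% and 57.4%, Vegfc CRE fibroblast-like cells 24.7% and macrophage-like cells 25.4%. The same filter gave −1.58 for proliferation in lymphatic endothelial-like cells, −1.79 for chondrogenic genes in tenocyte-like cells and 26.4 CPM of Vegfc in vascular endothelial-like cells of day 21.

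With each library clustered on its own, T/NK-like cells at day 0 were 43.7%, lymphatic endothelial-like cells at day 7 0.0%, muscle-like cells at days 7 and 21 36.1% and 28.7%, and Vegfc CRE fibroblast-like and macrophage-like cells 12.7% and 28.3%. In vascular endothelial-like cells of day 21 against day 7, proliferation turned to 4.31, lymphatic markers to −0.99, and Top2a, Mki67 and Stmn1 to 4.28, 4.35 and 2.28. In Vegfc CRE against day 7, Vegfc turned to 1.24, and against day 21 proliferation turned to −1.73 and Ube2c, Birc5 and Hist1h2ap to −1.94, −1.74 and −0.23. In fibroblast-like cells activated genes were 0.84 and resting genes −0.52, and chondrogenic genes turned to −4.64 and Acan to −0.76. In tenocyte-like cells chondrogenic genes turned to 1.45. By construction, this setting names different cells.

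With doublet calls kept in, muscle-like cells were 77.2% and 55.2% at days 7 and 21, lymphatic endothelial-like cells 12.4% at day 21 and Vegfc CRE macrophage-like cells 13.8%, with −1.50 for lymphatic proliferation and 0.59 for macrophage glycolysis. With the highest doublet scores removed (added), T/NK-like cells at day 0 were 53.8% and muscle-like cells at day 7 75.2%, with −1.57 for lymphatic proliferation and −1.30 for resting fibroblast genes. The naming rule at 75% (added) gave 4.93% and 9.33% lymphatic endothelial-like cells at days 7 and 21, and no naming rule (added) 21.2% fibroblast-like cells in Vegfc CRE.

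TMM gave −0.56 for interferon genes in cluster 2, −0.95 for inflammatory genes in muscle progenitor-like cells, 1.98 for tip genes in vascular endothelial-like cells of Vegfc CRE against day 7, 1.48 for activated and −1.15 for resting fibroblast genes. DESeq2 size factors gave −1.19 for lymphatic proliferation, and in the order above −0.56, −0.93, 1.96 and, for resting genes, −1.16. These moves follow from the shift in scale. Equal weight for each cell gave −1.66 for lymphatic proliferation, turned lymphatic dissociation genes to −0.19 and gave −0.99 for resting genes. With 1 UMI in each library, chondrogenic genes in muscle progenitor-like cells turned to 0.31 and inflammatory genes in Vegfc CRE vascular endothelial-like cells against day 7 to −0.23, and vascular proliferation was −1.13 at day 21 against day 7 and 1.86 in Vegfc CRE against day 21. With at least 50 UMIs vascular proliferation at day 21 against day 7 was −1.05. These moves come with a changed set of genes. In lymphatic endothelial-like cells, cluster 8 alone (added) gave −0.74 for proliferation and turned lymphatic markers to −0.01 and dissociation genes to −0.46, and cluster 2 included (added) gave −1.55 for proliferation.

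For the Vegfc test in fibroblast-like cells, DESeq2 called 2 genes, cells matched on depth (added) 15, only genes with no counts removed 98, and no replicate block 0 (39 unadjusted). DESeq2 size factors called 27 and doublet calls kept in 24. Not run were the thinned test, which left too few cells, and leaving out a library, which leaves no residual degrees of freedom. Cluster 2 was not followed through clustering anew, and its values under the stricter filter keep its cells as first clustered. Also, clustering each library on its own gave no comparison of lymphatic endothelial-like or macrophage-like cells. Depth limits how often Vegfc is seen, since thinning to 2000 UMIs left it in 1.88% of Vegfc CRE vascular endothelial-like cells against 9.44% before.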

Other observations

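The groups below were singled out only after their values were seen. Cluster 31, 25 cells all of day 0, carried genes of lymphoid stroma. Its defining genes included the chemokine genes Ccl19, Cxcl13 and Cxcl12, at 5294, 1460 and 9902 CPM, and a Vegfc UMI was seen in 60.0% of the cells and in 24% after thinning. Among genes not looked at before, Il7, a survival factor gene for lymphocytes, stood at 330 CPM against 1.43 in mural-like and fibroblast-like cells of the other libraries, Bst1 at 231 against 1.10, the alarmin gene Il33 at 469.6 against 61.1 and the adhesion gene Vcam1 at 682 against 117.

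Cluster 22, left unnamed, held 23 cells of day 7 and 144 of day 21 with the highest Prox1 of the groups described here, at 5623 and 3140 CPM. Cldn11, a tight junction gene of lymphatic valves, stood at 801 and 778 CPM, against 34.6 and 32.1 in cluster 2 and 8.07 and 28.3 in lymphatic endothelial-like cells. Efnb2, a ligand gene also needed for lymphatic valves, stood at 326 and 189.6 CPM, and Vegfc had no UMI. Cluster 16, with 151 and 111 cells, held the differentiation factor gene Myog at 1922 and 4634 CPM, the skeletal actin gene Acta1 at 1225 and 2501 and the stem cell gene Pax7 at 262.5 and 52.5. Cluster 20, with 195 cells of Vegfc CRE, held Mki67 at 225 CPM together with Acan at 181 CPM and Vegfc at 6.76 CPM. Genes that lead or define these clusters are not results.

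At day 0, 12.7% of 409 T/NK-like cells held a Prox1 UMI (23.1 CPM, 18.6 to 28.3, and 3.29% of cells after thinning), against 2.04% of 98 B/plasma-like cells, 7.14% of 56 dendritic-like cells (1.98 to 17.3%, and 1.79% after thinning) and 0 of 154 T/NK-like cells of Vegfc CRE, which allows up to 1.95%. Depth differed, at medians of 7059, 4860, 12124.5 and 3726 UMIs in this order. After thinning the intervals overlapped. They were 1.76 to 5.56% in T/NK-like cells of day 0. In B/plasma-like cells and in T/NK-like cells of Vegfc CRE they reached 3.93% and 2.62%. Scaled by depth without thinning, Prox1 stood at 3.79 CPM (0.459 to 13.7) in B/plasma-like cells and 5.57 CPM (1.52 to 14.3) in dendritic-like cells. It was 0 in T/NK-like cells of Vegfc CRE, with an interval up to 5.79 CPM. These intervals lay below that of T/NK-like cells of day 0. Osteoclast-like cells of Vegfc CRE held Vegfc at 9.92 CPM (4.76 to 18.2) in 14.6% of 48 cells, with none left after thinning.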
